A study of Mus musculus with 9 samples.

How the data were processed

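RNA from the dorsal telencephalon of single mouse embryos at embryonic day 12.5 was compared on 9 two-colour oligonucleotide arrays. Per the labels, 3 embryos were homozygous Fgfr1 mutants (HOM embryos 2, 4 and 7) and 3 were Fgfr1 heterozygous (HET embryos 1, 3 and 8). All 6 carried 1 copy of Cre recombinase in the Foxg1 locus, so all were heterozygous for Foxg1. Each array held 1 HOM and 1 HET embryo, every HOM embryo met every HET embryo once, and each embryo was therefore on 3 arrays. The HOM embryo was labelled with Cy3 on 5 arrays (1, 2, 7, 8 and 9) and with Cy5 on 4 arrays (3, 4, 5 and 6). RNA was extracted with Trizol, per the labels' protocols. Embryos are separate animals, and whether they shared a litter is not given in the sources used here.

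The deposited values are log2 ratios of the signals of both channels, 1 per probe and array. The scanner, image software, background correction and normalization used by the authors are not given in the sources used here, and single-channel signals were not used here. The log2 unit was read from the values: the deposited ratios stop at a ceiling of 16.61, which is log2 of 100000. What this ceiling stands for is not given in the sources used here. Between 100 and 170 values per array lay at this ceiling and were treated as missing, on the premise that they are placeholders and not measurements. A further 3190 to 5941 of the 21998 probes per array had no value. The deposited medians ran from -0.756 to 0.515 between arrays, so the table had not been centred. With no single-channel signals, a loess normalization over signal strength could not be made, and any trend of the ratio with brightness remains in the values. The ratio of 5 probes, those of H3f3a, Hba-a1 and Rpl41 among them, lay within 0.02 of 0 on at least 5 arrays, a possible mark of saturation.

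The design fixed before the data were examined had kept the deposited values as they were, on the premise that they were normalized. The arrays were not centred, whatever other normalization they had. Each array's log2 ratios were therefore centred on the median over its non-control probes before any gene test was looked at. The values as deposited became an alternative. Centring moved the median difference over all probes from -0.06 to 0.01, and the difference of any gene by about the same constant.

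The direction of the deposited ratio is not stated. The additive model of 6 embryo levels and a dye term left a median residual variance of 0.0788 over 9915 probes when ratios were read as running by dye, and 0.103 when they were read as already running HOM over HET. On this fit they were read by dye, and each array was turned to HOM over HET by its dye labels. The rule fixed beforehand named this fit and the correlation between arrays of opposite dye orientation. It also foresaw sizes and counts with no direction if the overall sign stayed unsettled. The sign did stay unsettled, and directions are given below only under the reading stated here. With an own term for arrays 1 to 3 the residual variances were 0.0679 by dye and 0.0686 as HOM over HET. Of the probes, 47.9% then fitted better by dye, so the fit alone did not settle the reading. Nor did other values: of all patterns of turning, the labelled one ranked 7 by the number of probes of 1 sign on all 9 arrays with a mean over 0.4 (18 probes, against 32 for another pattern). Before turning, the median correlation was 0.19 between arrays of opposite dye orientation and 0.13 between arrays of the same orientation. Ratios were taken as Cy5 over Cy3, the usual form with Cy5 as channel 2. The sample titles name hets against hom whatever the dye, and do not state how the ratio runs. Directions therefore rest on this convention and are not known. Under the inverse ratio every higher would be a lower and the reverse, with sizes and p-values as given. Had the ratios already run HOM over HET, 0 lists would pass in place of 4, 3 of these 4 would reverse, and 591 probes in place of 116 would have an unadjusted p under 0.05, with 0 past the adjustment.

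For each probe with values on at least 8 of 9 arrays (9915 probes on 9 and 2299 on 8), least squares on 6 embryo levels and a dye term gave 1 level per embryo. These levels, relative to the mean of the 6 embryos, entered limma 3.58.1 in R 4.3.3 (lmFit and eBayes), 3 HOM against 3 HET embryos, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The embryo was the replicate, not the array. Differences are log2 HOM minus HET with limma's moderated standard error (SE). In this pairing the error of an array enters the spread between embryo levels more strongly than the genotype difference, so the test is cautious. On simulated data with 12214 probes and the estimated spreads, 1.65% of unchanged probes had an unadjusted p under 0.05 and 0 were called. The test recovered 0 of 67 probes changed by 0.5 on the log2 scale, 10 of 67 changed by 1 and 39 of 66 changed by 2. Treating the 9 arrays as replicates recovered 24, 47 and 58 of these but called 19 unchanged probes, with 9.52% of unchanged probes under an unadjusted p of 0.05. The simulation gave all probes the same embryo SD (0.118), whatever their noise. In the data the array test had 546 of 12214 probes under an unadjusted 0.05, where chance gives 611. The simulated rate of false calls was therefore not shown to hold for the data.

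Gene lists were fixed before the data were examined: 22 lists of FGF signalling genes, cortical area and cell type markers, other tissues that a dissection could hold, stress, cell cycle and sex-linked genes, and the genes named by the design. Probes of a gene were averaged, and 21 lists with at least 3 measured genes were tested with limma's camera at its preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation and fry were run beside it. Each list was also set against 10000 random lists matched on the array residual. A simulated list whose members were lowered by 0.3 had an adjusted p of 1.45e-06, and 0 other lists were called. That size is above the median of each list called in the data, so recovery at the sizes found there was not shown. Simulated genes were also drawn independently of each other. In the data, the estimated correlation of the lists called ran from 0.018 for neuron markers to 0.165 for caudal cortical genes. The simulation therefore does not test false calls at the preset correlation of 0.01. Probe names came from the platform's annotation: 16632 probes had 1 gene symbol, 139 had several and 4995 had none, and 232 were controls. Of the named probes, 15952 were found by gene identifier in a table of mouse genes (assembly GRCm38.p6, used for names only) and 0 symbols changed. No coordinates are given, since the sources used here state no genome build.

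The text names genes by a rule fixed before the data were examined. It takes Fgfr1 and Foxg1, then up to 12 named probes per direction with 1 sign on every array, first those past the threshold and then the next by p. It adds list members past the threshold over all probes, and for each list the 2 members with the largest difference, or 4 for lists past the list test. Genes named outside this rule are marked as chosen after their values were seen.

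Chosen before the data were examined were alternatives with no dye term, the deposited values without centring, equal spread of arrays, other limits on missing values, each embryo and each array left out, and arrays as replicates with or without an embryo as random block. Others were embryos as fixed effects against array error, eBayes settings, 1 value per gene, each dye orientation alone and other list tests. A filter on dim probes was foreseen and not run, as it needs channel signals. Chosen after seeing the data were crossed random embryo effects, an own term for arrays 1 to 3, arrays 4 to 9 only, unturned ratios, ceiling values kept, the noisier probes left out and the FGF list without immediate-early genes. The gene test was run under 36 alternatives and the list test under 34, and the embryo test stayed the main one although it is cautious. Arrays 1 to 3 stood apart in their correlations, so values within arrays 1 to 3 and within arrays 4 to 9 are given beside the leading results.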

Results

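Gene expression in the dorsal telencephalon, the part of the embryonic forebrain that forms the cerebral cortex, was compared between 3 homozygous Fgfr1 mutant embryos (HOM) and 3 heterozygous embryos (HET) at E12.5. Fgfr1 encodes a receptor for fibroblast growth factors (FGFs), which pattern the cortex along its rostral to caudal axis. The 9 arrays gave between 15957 and 18708 usable log2 ratios each, and 12214 probes had values on at least 8 arrays. Spearman correlations of the centred ratios before turning lay between 0.24 and 0.34 among arrays 1 to 3, between 0.09 and 0.30 among arrays 4 to 9, and between -0.0033 and 0.21 across both sets. Directions below rest on reading the ratios as Cy5 over Cy3 and are not known. The list results and the results of single probes both rest on turning the arrays by their dye labels.

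Fgfr1, the gene targeted in these embryos, did not differ measurably at its only probe. The difference was 0.00 ± 0.17 (log2 HOM minus HET, SE, n = 3 and 3 embryos), and the HOM embryo was higher on 5 arrays and lower on 4. Embryo levels of Fgfr1 were 0.29, -0.23 and -0.06 in HOM embryos 2, 4 and 7, and 0.12, -0.16 and 0.04 in HET embryos 1, 3 and 8. The exact permutation test over 20 splits of the 6 embryos gave p = 1, where the smallest possible value is 0.1. The pairing on arrays makes the 20 splits unlike in their error, so this and the other exact permutation p-values are approximate. Whether this probe lies in the deleted part of the gene is not known, so it does not check the genotype labels. No probe was named for Foxg1, the locus that drives Cre in all 6 embryos.

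The question of the main comparison was which transcripts depend on Fgfr1 in the early cortex. Cux1, a homeodomain transcription factor of cortical progenitors and neurons, had the smallest p among named probes that were lower in HOM on every array, with a difference of -0.57 ± 0.12 (1.49-fold, n = 3 and 3 embryos) on 9 arrays. A second Cux1 probe gave -0.52 ± 0.37 and was lower on 7 of 9 arrays. The exact permutation test gave p = 0.2 for the mean of both Cux1 probes, and was not run on the first probe alone. Epha3, an ephrin receptor of axon guidance, had the smallest p among named probes that were higher in HOM on every array, with 0.35 ± 0.10 on 9 arrays. Both rankings hold only with the arrays turned by dye. Without turning, a probe of 1 sign on every array changes sign between the dye orientations, so Cux1 and Epha3 would be of mixed sign. No probe passed the test: 0 of 12214 probes had a limma adjusted p under 0.05, and the smallest adjusted p was 1. At an unadjusted 0.05 there were 116 probes, against 611 expected by chance from a test that is cautious in this design. Treating the 9 arrays as replicates also called 0 probes, with 546 under an unadjusted 0.05, and crossed random embryo effects called 0 with 290.

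Further named probes had 1 sign on every array without passing the adjustment. Higher in HOM were the teneurin adhesion gene Tenm2 at 0.54 ± 0.20 (0.26 ± 0.11 over its 3 probes), the cyclin-dependent kinase inhibitor Cdkn1c at 0.52 ± 0.20, the Notch target Hes1 at 0.38 ± 0.14 and the phosphatase Ptp4a1 at 0.38 ± 0.12. Cacna2d1, Map3k8, Muc2, Hdac2, Myo5a, Hnf4a and Nppb were also higher on every array, with differences between 0.20 for Hnf4a and 0.76 for Nppb. The other probes of Muc2 were of mixed sign over arrays, and its mean over 3 probes was 0.16 ± 0.11, higher on 7 of 9 arrays. Lower in HOM were the ETS transcription factor Etv1 at -0.47 ± 0.19, the carbonic anhydrase Car7 at -0.99 ± 0.28, the sterol synthesis enzyme Dhcr7 at -0.35 ± 0.12 and Tnf at -0.33 ± 0.11. Kif13b, Pantr2, Shmt1, Mpped2, Smc2, Rad9a and 2410012E07Rik were lower on every array, with differences between -0.16 for Rad9a and -0.90 for 2410012E07Rik. Second probes were of mixed sign for Kif13b (-0.38 ± 0.48, lower on 4 of 8 arrays) and Smc2 (0.05 ± 0.12, lower on 3 of 9). Of all probes, 64 had 1 sign on every array they were measured on, 46 of them named, where independent arrays give 57 by chance. The levels of all 3 HOM embryos lay on 1 side of all 3 HET embryos for 364 genes (3.73%), where exchangeable embryos give 10% by chance. The embryos are not exchangeable here, since each array sets a HOM against a HET embryo, and simulated probes with no difference gave 5.5%. Epha3 had 0.40 within arrays 1 to 3 and 0.31 within arrays 4 to 9, and Cux1 had -0.74 and -0.49.

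**Figure D1:**
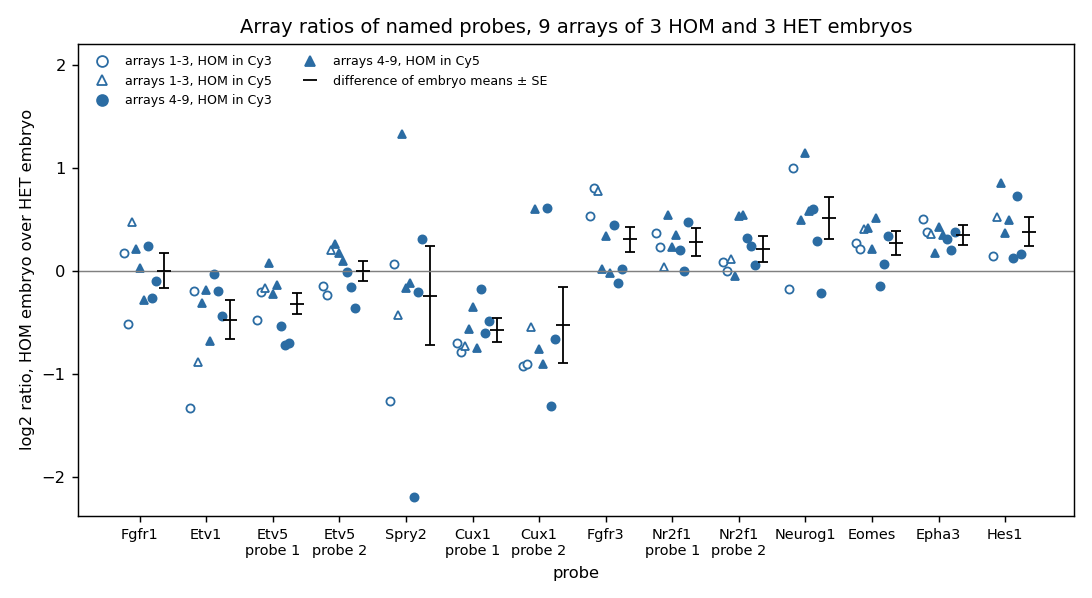
Log2 ratios of the HOM over the HET embryo (vertical axis) for 14 probes (horizontal axis) on the 9 arrays, with open symbols for arrays 1 to 3, filled symbols for arrays 4 to 9, circles for HOM in Cy3 and triangles for HOM in Cy5. Black bars give the difference of embryo means ± SE: Etv1 and the first Cux1 probe lie below 0 on every array, Epha3 and Hes1 above 0 on every array with a value, and Fgfr1 scatters around 0.

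Genes known as targets or feedback regulators of FGF signalling were lower in HOM as a group by camera at its preset correlation (adjusted p = 0.00937, limma). They missed the threshold with an estimated correlation (p = 0.0423, adjusted p = 0.444) and with fry (adjusted p = 0.768), and no single member passed. Of 11 measured members 9 were lower and 2 higher, with a median difference of -0.10 and a mean of -0.26. The members with the largest differences were the immediate-early genes Egr1 at -1.15 ± 0.78 and Ier2 at -0.58 ± 0.36, then Etv1 at -0.47 ± 0.19 and the feedback inhibitor Spry2 at -0.24 ± 0.48. Egr1 and Ier2 were of mixed sign over arrays (lower on 4 of 8 and 5 of 9), while Etv1 was lower on 9 of 9, with -0.82 within arrays 1 to 3 and -0.31 within arrays 4 to 9. Etv5, a further ETS factor downstream of FGF receptors, was chosen after its values were seen: its probes disagreed, with -0.32 ± 0.10 at one and 0.00 ± 0.10 at the other, and their mean was -0.16 ± 0.09. Etv4 of the same family, also chosen after its values were seen, had 0.01 ± 0.10.

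At the preset correlation 4 of 21 lists passed camera, the FGF targets among them, against 0 with an estimated correlation and 0 with fry. Had the deposited ratios already run HOM over HET, with no turning by dye, 0 lists would pass and the direction of FGF targets, neurogenic and neuron markers would reverse. With the values as deposited, without centring, 2 of the 4 passed, the FGF targets and feedback genes and the Caudal cortical genes, both at an adjusted p of 0.0226. Without HOM embryo 7 none of the 4 passed, and the FGF targets and feedback genes had an adjusted p of 0.211. No member passed over all genes (0) or adjusted over the list alone (0). The median was -0.12 within arrays 1 to 3 and -0.11 within arrays 4 to 9, but the list fitted on arrays 4 to 9 only had an adjusted p of 0.271 and a median of -0.03. Leaving out 1 embryo or 1 array gave adjusted p between 0.00227 and 0.238, and over all alternatives between 0.00227 and 0.927.

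Genes with higher expression in the caudal cortex were higher in HOM as a group by camera at its preset correlation (adjusted p = 0.0454), and missed the threshold with an estimated correlation (p = 0.147, adjusted p = 0.562). Of 9 measured members 6 were higher, and the median difference was 0.25. Fgfr3, an FGF receptor enriched caudally, had 0.31 ± 0.12 and was higher on 7 of 9 arrays. The transcription factors Nr2f6, Emx1 and Emx2 had 1.32 ± 1.04, 0.64 ± 0.70 and 0.29 ± 0.23, differences about as large as their errors. Nr2f1 (COUP-TFI), a determinant of caudal area identity named here after its values were seen, had 0.25 ± 0.10 over 2 probes and its mean was higher on 9 of 9 arrays. Within arrays 1 to 3 Fgfr3 had 0.72 and within arrays 4 to 9 it had 0.12, while Nr2f1 had 0.13 and 0.29. The median of the list was 0.13 within arrays 1 to 3 and 0.12 within arrays 4 to 9, and without HET embryo 3 its adjusted p was 0.86, in a range of 0.00511 to 0.927 over all alternatives.

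Genes with higher expression in the rostral cortex did not pass as a group. Of 9 measured members 5 were lower and 4 higher, the mean difference was -0.09, the median was -5.21e-06, and camera gave an adjusted p of 0.0835 in the lower direction (p = 0.133, adjusted p = 0.562 with an estimated correlation). The list shares Etv1, Etv4 and Etv5 with the FGF target list. Apart from Etv1, its largest difference was -0.16 ± 0.13 for Mest, an imprinted gene.

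Markers of neurogenic and intermediate progenitors were higher in HOM by camera at its preset correlation (adjusted p = 0.0454), and missed the threshold with an estimated correlation (p = 0.0767, adjusted p = 0.537). Of 14 measured members 9 were higher, and the median difference was 0.08. Ribosomal protein genes (median 0.06), radial glia markers (0.06) and erythroid markers (0.11) had medians in the same direction. The proneural gene Neurog1 had 0.51 ± 0.20 and was higher on 6 of 8 arrays, Eomes (Tbr2), a marker of intermediate progenitors, had 0.27 ± 0.12 on 8 of 9, and Neurog2 had 0.26 ± 0.15 on 7 of 9. Neurod4 had -0.41 ± 0.76 in the other direction. The exact permutation test gave p = 0.1, the smallest that 20 splits allow, for Neurog1 and Eomes, as for Etv1, Fgfr3 and Epha3. No member passed over all genes (0) or adjusted over the list alone (0). Its median was 0.12 within arrays 1 to 3 and 0.09 within arrays 4 to 9, but the list fitted on arrays 4 to 9 only did not pass. With 1 embryo or 1 array left out it passed in 4 of 15 fits. With the values as deposited its adjusted p was 0.11, and alternatives ranged from 0.00967 to 0.89.

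Neuron markers were also higher in HOM by camera at its preset correlation (adjusted p = 0.00937), and missed the threshold with an estimated correlation (p = 0.0348, adjusted p = 0.444). Of 30 measured members 24 were higher, and the median difference was 0.12. The largest differences were those of Syt1 at -0.36 ± 0.35, Zic1 at 0.28 ± 0.24, L1cam at 0.27 ± 0.49 and Bcl11b at 0.25 ± 0.29, all within or near their errors. The probes of Bcl11b disagreed, with 0.00 ± 0.18 and 0.51 ± 0.45. Members with smaller errors, chosen after their values were seen, were the growth cone gene Gap43 at 0.23 ± 0.11 and Crmp1 at 0.18 ± 0.09, each higher on 8 of 9 arrays. No member passed over all genes (0) or adjusted over the list alone (0). Its median was 0.09 within arrays 1 to 3 and 0.04 within arrays 4 to 9, and the list fitted on arrays 4 to 9 only did not pass. With 1 embryo or 1 array left out it passed in 9 of 15 fits. With the values as deposited its adjusted p was 0.079, and alternatives ranged from 0.00511 to 0.927. The 68 ribosomal protein genes measured, which are abundant transcripts, had a median difference of 0.06 in the same direction, and erythroid markers had one of 0.11.

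**Figure D2:**
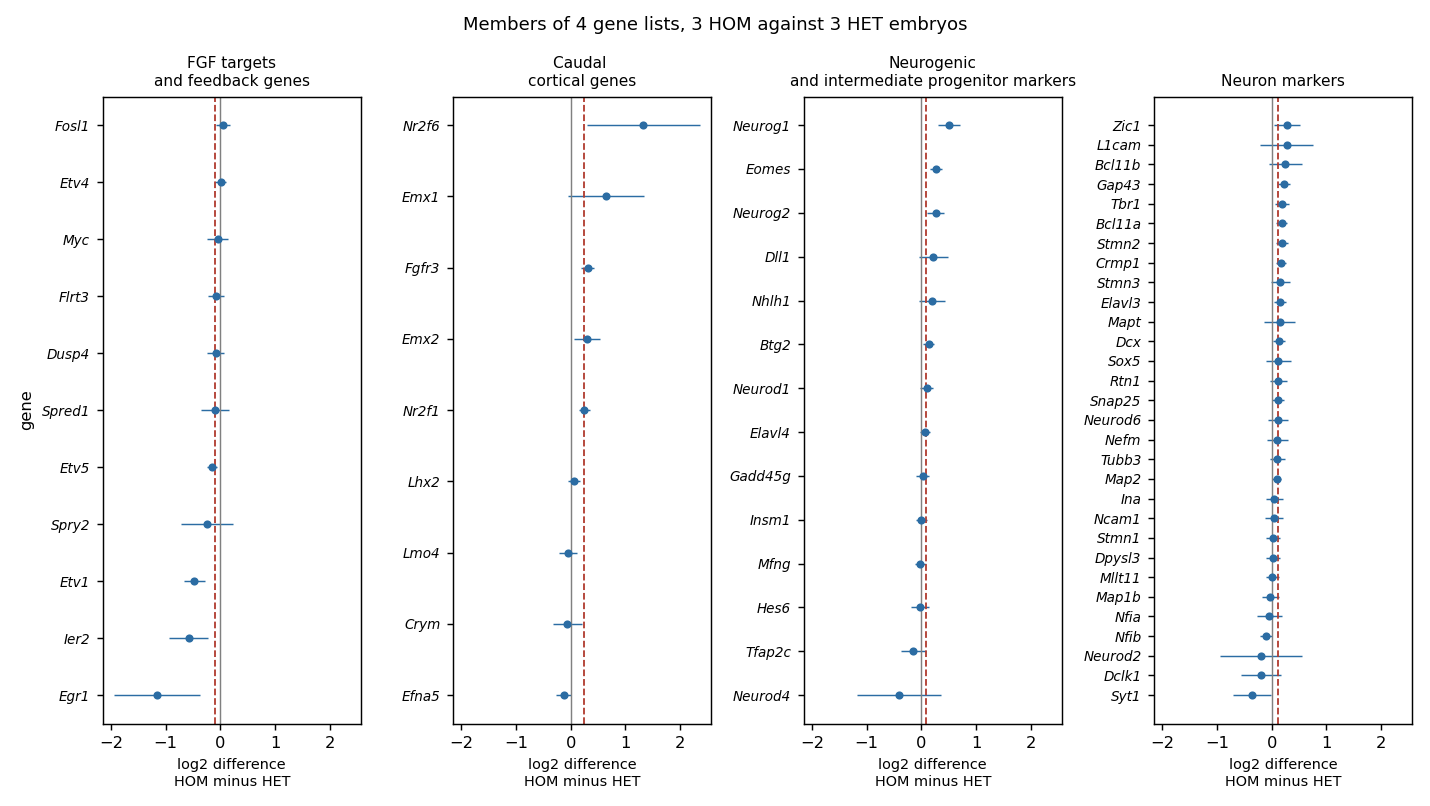
Log2 differences HOM minus HET (horizontal axis) of the measured members (vertical axis) of the 4 gene lists past the camera test at its preset correlation, with bars of 1 SE from 3 HOM and 3 HET embryos and a dashed line at each list's median. Of the FGF targets 9 of 11 lie below 0, and 24 of 30 neuron markers lie above 0, most by less than their errors.

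The other lists did not pass. Radial glia and neuroepithelial progenitor markers were higher for 16 of 19 members, with a median of 0.06 and a camera adjusted p of 0.0835, and the examples were Gli3 at 0.65 ± 0.65 and Notch1 at 0.52 ± 0.45. Erythroid markers, a sign of blood in the dissection, were higher for 8 of 10 members with an adjusted p of 0.0835, with Epb42 at 0.36 ± 0.27 and Alas2 at 0.28 ± 0.27. Cajal-Retzius cell markers were higher for 7 of 8 members (adjusted p = 0.107), led by Cacna2d2 at 0.48 ± 0.73 and Eomes at 0.27 ± 0.12, which entered this list under its older symbol and also belongs to the intermediate progenitor list. Diencephalon and eye markers were lower for 9 of 11 members (adjusted p = 0.236), with Rax at -0.71 ± 0.66 and Nkx2-2 at -0.25 ± 0.58. Ventral telencephalon markers, the neighbouring territory, had a median of 0.05 and an adjusted p of 0.91, with Rarb at -0.37 ± 0.44 and Dlx1 at 0.29 ± 0.36.

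Among FGF ligands and receptors 7 of 10 genes were higher (adjusted p = 0.91), and the largest differences were -0.76 ± 0.32 for Fgfr4 and -0.45 ± 0.37 for Fgf7. Fgfr4 was lower on only 5 of 9 arrays, with -4.34 on array 3, -2.44 within arrays 1 to 3 and -0.10 within arrays 4 to 9, and without array 3 its difference was -0.22. Cell cycle genes were split evenly, 17 higher and 17 lower, with a median of 0.00 and an adjusted p of 0.91, and held Cdkn1c and Tk1, the latter at -0.33 ± 0.25. Eph and ephrin genes had 6 higher and 7 lower (adjusted p = 0.91), Epha3 at 0.35 and Efnb1 at -0.34 ± 0.46 being the largest. The list of hem, WNT and BMP genes had a median of -0.04 (adjusted p = 0.909), with Wnt2b at 1.44 ± 1.15 and Bmp6 at -0.68 ± 0.38. Apoptosis and p53 response genes had an adjusted p of 0.91 with Sesn2 at -0.36 ± 0.47 and Fas at -0.31 ± 0.26, and hypoxia and glycolysis genes one of 0.91 with Slc2a3 at -0.54 ± 0.57 and P4ha1 at -0.47 ± 0.55. Markers of other tissues had adjusted p of 0.91 for mesenchyme and meninges (Twist1 -0.57 ± 0.54 and Foxc2 -0.57 ± 0.27), 0.834 for endothelium (Cdh5 -0.17 ± 0.13 and Tie1 -0.15 ± 0.09), 0.91 for macrophages and leukocytes (C1qb -0.52 ± 0.66 and Cd68 0.22 ± 0.22) and 0.91 for surface epithelium (Epcam 0.54 ± 0.73 and Krt5 -0.28 ± 0.49). Camera compares the moderated statistics of a list with those of the other genes, and its direction differed from the sign of a mean or median for some lists. These were FGF ligands and receptors (mean -0.04, median 0.08, camera higher), ventral markers (mean 0.00, camera higher), hem, WNT and BMP genes (mean 0.00, camera lower), mesenchyme (median 0.00, mean -0.05, camera lower) and endothelium (median 0.06, mean 0.00, camera lower). Others were macrophages (median -0.03, mean -0.04, camera higher) and surface epithelium (median -0.03, mean 0.01, camera lower). The sex-linked genes were a further one (median 0.03, mean -0.11, camera higher). For Eph and ephrin genes the mean (-0.03) and median (-0.07) went with camera (lower), and only the mean statistic (0.0193) did not. In each of these lists 0 members passed, over all genes or adjusted over the list alone.

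Differences between embryos of a genotype were small beside the noise of single arrays. The median residual SD of an array was 0.34 on the log2 scale, and the median SD between embryos after taking off array error was 0.118. The ratio of the variance of embryo levels to the residual variance was 0.454, of which array error alone accounts for the larger part. For the dye effect 0 of 12214 probes passed an adjusted 0.05 in limma. There were 1360 under an unadjusted 0.05, where chance gives 611, so the 0 does not show that a dye effect was absent. Its median absolute size was 0.13, beside 0.10 for the genotype difference. Without centring of the arrays 55 probes passed for the dye effect.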

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

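The criterion was chosen before the values were seen. Within the arrays of 1 dye orientation, 21 of 145 sets of values held an array far from the others by Dixon's criterion, where chance gives about 1 in 20, or 7. That chance holds for unselected sets. Many of the probes tested had been picked for a large difference in these data, which favours probes with 1 extreme array. Part of the excess may therefore come from selection. Array 3 accounted for 7 of the 21. Those on array 3 were the log2 ratios of Rarb (-3.2), Nr2f6 (-2.49), P4ha1 (-3.51), Epcam (4.68), C1qb (0.53), Fgf7 (-1.19) and Cacna2d2 (4.44). On array 4 they were Cacna2d1 (0.024), Zic1 (1.49), Neurod4 (-4.47) and Krt5 (-2.58), and on array 5 Syt1 (-1.13). With HOM in Cy3, array 1 stood apart for Nkx2-2 (-4.88) and C1qb (-3.86), and array 2 for Slc2a3 (-4.07), Syt1 (-2.04), Cacna2d2 (1.38) and Fgfr4 (-1.51). Array 7 stood apart for Tnf (-0.0955) and array 8 for Hes1 (0.73) and Myo5a (0.146). Differences of these genes depend partly on 1 array, which did not always add to them. The values of Nr2f6 and C1qb on array 3 ran against their differences. Those of Tnf, Myo5a and Cacna2d1 were the nearest to 0 within their dye orientation.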

How the results depend on the processing

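Arrays 4 to 9 only, an own term for arrays 1 to 3, crossed random embryo effects, ceiling values kept, unturned ratios, no immediate-early genes and noisier probes left out were chosen only after the result was seen. The count of probes past 0.05 was 0 under all 36 alternatives, and the count at an unadjusted 0.05 ran from 21 (without HOM embryo 4) to 1122 (only the 4 arrays with HOM in Cy5). Fgfr1 passed under none of its 30 alternatives and ran from -0.17 to 0.12 with an embryo or array left out. The number of lists past 0.05, 4 in the report, was 2 as deposited, at equal spread, on probes with all 9 arrays, with no filter on missing values, with ceiling values kept and on arrays 4 to 9. It was 1 with noisier probes left out and 0 with an estimated correlation, fry or unturned ratios. With 1 embryo or array left out it ran from 0 (HOM embryo 7, array 2 or array 5) to 5. Single-channel signals were not used here, so a filter on dim probes was not run. The cause of the changes below was not tested.

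FGF targets and feedback genes had adjusted p of 0.444 (estimated correlation), 0.768 (fry), 0.0635 (all 9 arrays), 0.271 (arrays 4 to 9), 0.221 (noisier probes out), 0.0454 (no immediate-early genes) and 0.0103 (crossed random effects), and 0.00227 to 0.238 with an embryo or array left out. Caudal cortical genes had 0.562 (estimated correlation), 0.768 (fry), 0.0584 (equal spread), 0.244 (no missing filter), 0.0556 (1 probe per gene), 0.0583 (ceiling kept) and 0.927 (unturned), left-out range 0.0208 to 0.86, and too few genes with noisier probes out. Neurogenic and intermediate progenitor markers had 0.537 (estimated correlation), 0.768 (fry), 0.11 (as deposited), 0.0584 (equal spread), 0.0961 (all 9 arrays), 0.081 (no missing filter), 0.105 (ceiling kept), 0.0549 (own term), 0.308 (arrays 4 to 9) and 0.2 (noisier probes out), left-out range 0.00967 to 0.631. Neuron markers had 0.444 (estimated correlation), 0.768 (fry), 0.079 (as deposited) and 0.136 (arrays 4 to 9), left-out range 0.00901 to 0.251. Unturned ratios reversed the direction of FGF targets (0.927), neurogenic (0.89) and neuron markers (0.927).

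Lists that had not passed did so in a few settings: Radial glia and neuroepithelial progenitor markers without a dye term (0.0491), Erythroid markers with embryos as fixed effects (0.0468), and Rostral cortical genes with arrays as replicates (0.0491), the HET embryo as block (0.0468), an own term for arrays 1 to 3 (0.0472) and arrays 4 to 9 (0.0303). Left-out ranges were 0.0713 to 0.631, 0.00242 to 0.951 and 0.0426 to 0.69, and 0.025 to 0.686 for Cajal-Retzius cell markers. The variance ratio of embryos to arrays was 0.365 without a dye term, and 55 probes passed for the dye effect as deposited.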

Other observations

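The tests of the noise level of listed genes, of ventral telencephalon and of the difference between both sets of arrays were chosen only after the result was seen, and so were the error used for ribosomal protein genes and the comparison with erythroid markers. Beyond the groups above, a set of probes without a gene name was higher in HOM on all 9 arrays. Of 1305 unnamed probes measured on every array, 13 lay above 0 on all 9 with a mean over 0.5, and 0 lay below 0 with a mean under -0.5. Among 8610 named probes these counts were 3 and 1 (Fisher's exact test of the higher counts, unnamed against named, p = 1.28e-09; probes are not independent and the group was noticed in the same data). The 13 probes had differences from 0.50 to 0.83 with a median of 0.646, and the smallest limma adjusted p was 1. Their mean level was 0.156, 0.311 and 0.485 in HOM embryos 2, 4 and 7, and -0.159, -0.303 and -0.491 in HET embryos 1, 3 and 8.

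Chance and position were weighed for these unnamed probes. Among all ways to turn 4 of the 9 arrays only 1, the labelled one, gave as many such probes, and the highest other gave 6, but the group was noticed under the labelled turning, and over all probes with a mean over 0.4 that turning ranked only 7 (18 probes, the highest other 32). Other probes within 10 numbers of them in the probe numbering (70 probes) had a median difference of 0.05 ± 0.02 (error from resampling probes, not embryos). This argues against an effect of immediate neighbours, as far as the numbering follows the print. Most of the 13 lay between CG_Mm_EXT_3100699_1 and CG_Mm_EXT_3102927_1, in a numbering that reaches at least CG_Mm_EXT_3114294_1. A window of 10 numbers cannot exclude an effect of such a wider block or class of probes. With genotype and dye taken off, the ratios of the 13 rose and fell together. Their mean correlation was 0.52, against at most 0.12 in all but the highest few percent of 1000 random sets. Embryo levels remain in these residuals, and the random sets were not matched on signal or noise, so this correlation does not single out a shared sequence. A candidate explanation, not tested by sequence, is that most of them read 1 shared sequence, such as a repeat or a family of transcripts, that differs between these embryos. Whether genotype, strain background or litter sets it stays open and was not tested.

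The real split of the embryos gave 4 lists past 0.05 and the highest of the other 9 splits gave 2 (1 of 10 splits as many), but 10 splits are too few for a share under 0.05. In the fit with arrays as replicates, 1 of 100 assignments of the dyes, the labelled one, gave as many lists (5, the highest other 4). Other assignments drawn therefore did not give as many lists in that fit. It used the preset correlation, the labelled turning did not stand out over all probes, and the count does not bear on genotype by itself. All 4 lists lay in the outer tails of random lists matched on array residual, but so did 4 lists that had not passed, and the 4 had been chosen by much the same statistic, so a part of the noise level of the listed genes stays open. A first test of the difference between the 2 sets of arrays asked only whether medians kept their sign (4 of 4 did) and was replaced, once seen, by a stricter one: 1 of the 4, the caudal list, passed on arrays 4 to 9 alone, so a part played by arrays 1 to 3 cannot be told apart with so few arrays. That loss of Fgfr1 changes FGF target, caudal and neurogenic genes remains a hypothesis. No single gene passed, an estimated correlation ended every list call, and unturned ratios left 0 lists. The direction of any such change is not known, since under the inverse ratio every higher would be a lower.

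For the neuron list, abundant transcripts and tissue were weighed. Ribosomal protein genes had a median difference of 0.0639, below the 0.115 of neuron markers by slightly more than 2 standard errors of the difference (0.0233, widened after the value was seen). Erythroid markers, which include the abundant globins, had 0.113 ± 0.0556. The errors of medians in this paragraph come from resampling genes as if independent. They do not measure the spread between embryos, so these comparisons are not tests over embryos. Erythroid markers can also reflect blood in the dissection and include genes other than globins, so they do not isolate abundance. A shift of abundant transcripts was therefore not excluded as a source of part or all of the neuron list. It was not tested for the neurogenic list, whose median was 0.0849. Ventral telencephalon markers had a median of 0.0483 ± 0.0444, too wide to exclude a larger share of ventral tissue in the HOM dissections. A difference in developmental pace between embryos was not tested.

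The real split of the embryos gave 116 probes under an unadjusted 0.05, while the other splits gave 319 to 1869, so 10 of 10 splits gave as many. Simulated embryos with no group difference gave 146 for the real split and 586 to 881 for the others, because each array sets a HOM against a HET embryo and the splits are not alike in their error. The split of HOM embryo 2 and HET embryos 1 and 3 against the rest gave 1869, with 5 probes past an adjusted 0.05, and that of HOM embryos 2 and 7 and HET embryo 1 gave 1170, with 3. Of the 9 other splits 3 lay above the simulated range (889, 1170 and 1869) and 6 below it (319 to 573), so the simulation, with 1 spread for all probes, did not describe the splits on either side. In this simulation the pairing on arrays alone gave the other splits several times the count of the real one. It did not reach the measured 1170 and 1869, so pairing alone was not shown to give these.

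Sex-linked genes varied between embryos within both genotypes. Of the genes in this paragraph Uty, Kdm5d, Eif2s3y, Zfy1, Zfy2, Sry, Ddx1 and Clip1 were chosen after their values were seen. The level of Xist, the transcript that silences an X chromosome in females, was 1.10 in HOM embryo 4, 0.64 in HET embryo 3, 0.53 in HET embryo 8 and 0.21 in HET embryo 1, against -0.73 in HOM embryo 2 and -1.75 in HOM embryo 7. The Y-linked gene Uty had 0.82 in HOM embryo 2, 0.74 in HET embryo 1, -0.04 in HOM embryo 7, -0.37 in HET embryo 3, -0.47 in HOM embryo 4 and -0.67 in HET embryo 8. Kdm5d, also on the Y chromosome, had 0.68, 0.89, 0.08, -0.31, -0.77 and -0.58 in that order of embryos. HOM embryos 2 and 7 and HET embryo 1 were the 3 embryos lowest in Xist and highest in Uty and Kdm5d, the same split that gave 1170 probes, and 1 of the 3 probes past the threshold in that split was that of Tsix, the antisense transcript of Xist (-1.43 ± 0.09), beside Ddx1 (1.84 ± 0.09) and Clip1 (1.48 ± 0.10). Eif2s3y followed this split too (0.30, 0.04 and 0.18 in these embryos, at most -0.02 in the others), but the Y-linked genes Zfy1 (0.17, -0.21 and -0.23), Zfy2 (-0.07, 0.27 and -0.08) and Sry (0.02, 0.12 and -0.08) did not. These embryos are 2 of 3 HOM and 1 of 3 HET, and whether sex contributes to differences between the genotypes was not tested. The list test of sex-linked genes joins genes that move in opposite ways with sex, so its adjusted p of 0.91 says nothing of this.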
